A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

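The series holds 2 samples of Saccharomyces cerevisiae, a wild type strain (BY4742) and a mutant strain (LMA587), each with 1 3′ Long-SAGE library. Per the labels' protocols, poly(A)+ RNA of the wild type was selected on oligo(dT) beads and RNA of the mutant through TAP-tagged Cbp20. Tags of 18 nt were released with the enzyme MmeI and ligated into chains with a linker that marks the condition. The deposited values are counts, the number of times the authors saw each distinct tag in a condition, with a genome position and strand for each. They are whole numbers without normalization, as the values themselves show. The aligner, the genome build and any filter of the authors are not given in the sources used here. The numbers 1 and 2 of the conditions were paired with the strains through the labels' growth protocol.

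Each tag sequence was matched again, exactly and on both strands, to the S288C genome (reference R64), and the RNA end was taken from the match. Among 47511 distinct tags with a single match, all lay on the chromosome and strand given in the file. Of these, 6720 lay at the same coordinate, and the rest were shifted by up to 362 nt, so deposited positions were used for nothing else. Tags that matched at more than 1 place (1042 wild type and 1820 mutant tags) and tags with no match (31 and 99) were left out of the comparisons. The libraries kept 54888 and 73096 tags. The depth sets the precision: sequences seen once made up 17.6% of the wild type and 31.1% of the mutant tags, and a count of 0 allowed up to 3 counts of the total.

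The design, the gene lists, the named genes and 35 of the alternatives were fixed before the data were examined. Each end went to the first class that applied on the strand of the RNA. The classes were, in order, rRNA, tRNA (gene to 50 nt downstream), other annotated noncoding RNA (gene to 300 nt downstream), mRNA 3′ end (last 100 nt of the ORF to 300 nt downstream), ORF interior sense and ORF antisense. The remaining ends were divergent (within 500 nt upstream of an ORF start on the opposite strand), tandem (the same on its own strand) or elsewhere outside genes. Shares of tags have Wilson 95% intervals, and ratios of shares exact conditional binomial (Clopper-Pearson) 95% intervals. A gene counted its sense tags, and it was called higher or lower with at least 10 tags over both libraries, a ratio of at least 4 either way and an interval bound beyond 2. Shares were scaled by all placed tags. Folds against 0 counts used a floor of 3 counts in that library.

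The gene lists were ribosomal proteins, translation factors, ribosome biogenesis, glycolysis, histones, heat shock and stress, mating-type specific genes, phosphate and galactose genes, nucleotide synthesis genes with upstream start sites, Nrd1, exosome and TRAMP components, snoRNAs, snRNAs, tRNAs, the mitochondrial genome, meiosis, Ty elements, intron-containing genes and the label check genes. For each list with tags the median log2 ratio, with 0.5 tags added, was ranked among 10000 random lists of the same size matched in 20 bins of abundance. Percentiles outside 2.5 and 97.5 were counted, without a p-value. The mitochondrial genome was read as a class only. Ends outside genes or antisense were joined into clusters at gaps of up to 50 nt on a strand, and clusters with at least 5 tags were compared at 4 times the share. The spread of ends used clusters with 20 or more tags, thinned to 20 with a fixed seed.

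Named genes followed a rule. It took the label check genes, the 10 called genes highest and the 10 lowest by the interval bound nearest 1, the 4 members of each list with most tags, fixed loci of cryptic transcription, and the 6 clusters with most mutant tags in each class outside genes and in ORF antisense. Of the fixed loci, NEL025C is not in the annotation and was not analysed. The text names the members of the rule that matter and says where a gene was chosen after its values were seen.

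Counting and intervals used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9. The scalings TMM (edgeR 4.0.16) and size factors (DESeq2 1.42.0), run in R 4.3.3, served as alternatives. The procedure was tested on simulated data with 6413 genes, of which 50 each were changed 4-, 8-, 16- and 32-fold. It called 44%, 96%, 100% and 100% of them, with 0 in the wrong direction, and 0 of 939 unchanged genes with 10 tags. Both simulated libraries held counting error only, and the changed genes had an expected total above the minimum for a call. The simulation thus cannot show how often spread between libraries would give false calls. The true fold lay inside the interval for 195 of 200 changed genes. All 465 simulated tags with a single match returned their end and strand, and 500 of 500 positions got the same class from a separate implementation. Of 100 random lists 4 fell outside the percentile limits, while a planted list reached percentile 100.

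The alternatives changed the counting of tags, the windows, the scaling, the minimum of tags, the fold, the gap of clusters and the tags added before the log2, and 14 more were added after the data were seen. No test across conditions was made, since each group has 1 library.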

Results

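RNA 3′ ends were counted in budding yeast with 3′ Long-SAGE, a method that sequences a short tag from the end of each polyadenylated RNA. The 2 libraries came from 2 strains, with 1 library per group. The wild type poly(A)+ library held RNA of strain BY4742 grown in rich medium (YPD) and purified on oligo(dT) beads. The mutant CUT fraction library held RNA of strain LMA587, which lacks the nuclear exosome nuclease RRP6 and carries the poly(A) polymerase gene TRF4 (PAP2) under a tetracycline-regulated promoter. These cells grew in YPD with 10 µg/ml doxycycline for 16 h, and their RNA was purified through TAP-tagged Cbp20, a subunit of the nuclear cap-binding complex. CUT stands for cryptic unstable transcript, the class of short-lived RNA named in the title of the series. The wild type library held 55961 tags of 15532 distinct sequences, and the mutant library 75015 tags of 33173 distinct sequences. Of these, 54888 wild type tags (98.1%) and 73096 mutant tags (97.4%) matched the S288C genome (reference R64) at a single place and were used.

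Without replicates no comparison could be held against the spread between libraries, so no p-value is given. The intervals are 95% intervals that cover counting error only, and the tags carry no molecular identifiers. Each ratio is the share of tags in the mutant library over that in the wild type library. It compares these 2 libraries, which differ in strain, medium and RNA selection at once. A count of 0 allowed a share of up to 0.00547% in the wild type and 0.00410% in the mutant library.

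The genes named in the genotypes were read first. RRP6 (chromosome XV, 326832 to 329033), deleted in the mutant, had 1 wild type and 15 mutant tags, all of them in its 3′ end window and 0 in the ORF interior of either library. These counts left the deletion unchecked. PAP2, the repressible polymerase gene, had 0 wild type and 9 mutant tags, 8 of them inside the ORF, and these counts did not show its repression. CBC2, which encodes Cbp20, had 11 wild type tags and 1 mutant tag, all in its 3′ end window, a ratio of 0.0683 (0.00159 to 0.470). The auxotrophic marker HIS3 had 4 wild type tags and 1 mutant tag, while URA3, LEU2 and LYS2 had 0 tags in both libraries.

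The first comparison asked which kinds of RNA ended in each library. Ends outside annotated genes or antisense to ORFs took 49.6% (49.3 to 50) of the mutant tags and 7.46% (7.25 to 7.69) of the wild type tags, a ratio of 6.65 (6.44 to 6.87). Within them, antisense ends rose from 2.09% to 21.0% (ratio 10.0, 9.44 to 10.7). Ends within 500 nt upstream of an ORF rose from 1.53% to 8.89% on the strand of the ORF (tandem, ratio 5.80, 5.40 to 6.24). They rose from 1.81% to 6.67% on the opposite strand (divergent, ratio 3.69, 3.44 to 3.95). Annotated noncoding RNAs took 23.3% (23.0 to 23.6) of the mutant and 0.667% (0.602 to 0.738) of the wild type tags, a ratio of 35 (31.6 to 38.9). Ends in the 3′ end window of mRNAs fell from 86.6% (86.3 to 86.9) to 15.8% (15.6 to 16.1), a ratio of 0.183 (0.179 to 0.186). Sense ends inside ORFs took 5.17% of the wild type and 11.1% of the mutant tags, a ratio of 2.15 (2.06 to 2.24).

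**Figure D1:**
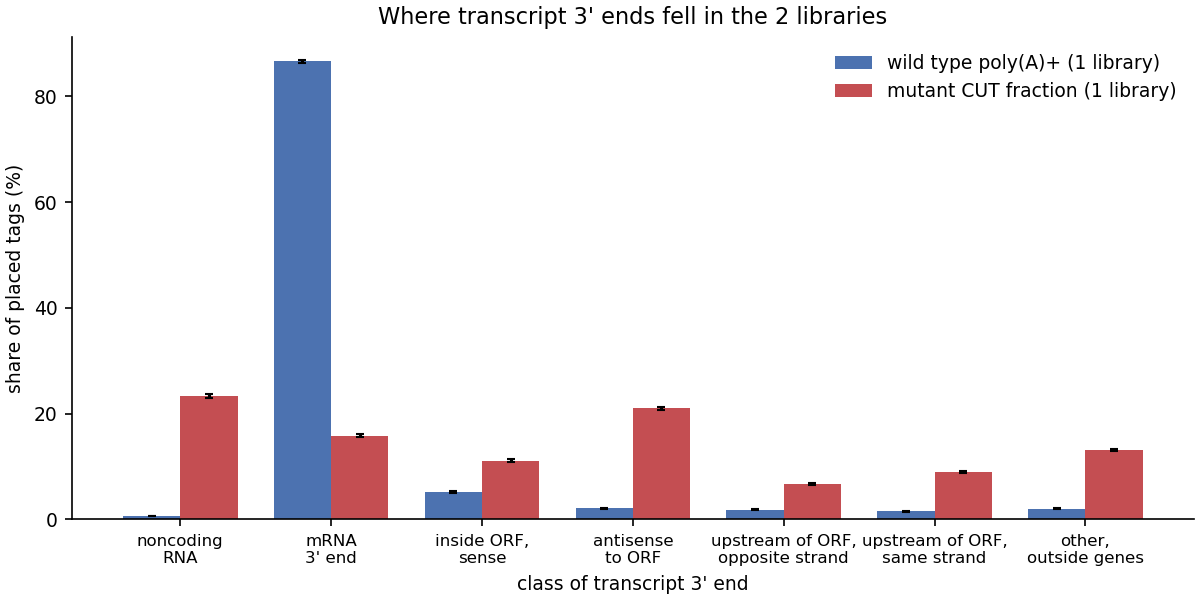
Share of tags (percent, vertical axis) in each class of RNA 3′ end for the wild type poly(A)+ and the mutant CUT fraction library; bars are single libraries and error bars Wilson 95% intervals of the counts. The mRNA 3′ end class held 86.6% of the wild type and 15.8% of the mutant tags, and annotated noncoding RNAs 0.667% and 23.3%.

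Small nucleolar RNAs (snoRNAs), the guides of ribosomal RNA modification, took 15% of the mutant and 0.525% of the wild type tags, a ratio of 28.6 (25.5 to 32.3). The spliceosomal snRNAs took 7.91% and 0.0820%, a ratio of 96.5 (72 to 132). The RNA subunit of the signal recognition particle, SCR1, had 98 mutant and 2 wild type tags, a ratio of 36.8 (9.92 to 308). RPR1, the RNA subunit of RNase P, had 23 and 2, a ratio of 8.64 (2.13 to 75.6). The telomerase RNA went the other way, with 3 mutant and 7 wild type tags, a ratio of 0.322 (0.0537 to 1.41), an interval that includes 1. Among tags with a single match, mature ribosomal RNAs had 0 in both libraries, tRNA genes 27 wild type and 46 mutant tags, and the mitochondrial genome 10 and 25. Left out here were 38 wild type and 285 mutant tags that matched at more than 1 place, all in tRNA genes or just after them. The reference holds each ribosomal RNA gene more than once, so the limit to single matches may set their count of 0. Between the ribosomal RNA genes on chromosome XII, the spacer held 3025 mutant and 39 wild type tags outside genes, a ratio of 58.2 (42.5 to 82.1). The spacer and the genes around it are repeated many times in the cell, while the reference holds few copies. The ratio of 6.65 for ends outside genes or antisense was 3.18 when the mRNA window ended 200 nt after the stop codon instead of 300 nt. Counting each distinct end once, it was 3.77, and the ratio of noncoding RNA ends was 5.33, against 91.7 without sequences seen once.

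The next comparison asked which genes gave more or fewer sense tags. Of 1034 genes with at least 10 tags over both libraries, 122 had a share at least 4 times higher in the mutant library and 351 at least 4 times lower, with the interval bound beyond 2. The 122 comprised 52 snoRNAs, 5 snRNAs, 6 other noncoding RNAs and 59 ORFs, and all 351 were ORFs. The gene furthest from equal shares was SNR37, a snoRNA on chromosome X (228094 to 228479), with 773 mutant and 2 wild type tags, a ratio of 290 (80.1 to 2401). LSR1, the U2 snRNA on chromosome II (680688 to 681862), had 3559 and 24 tags, a ratio of 111 (74.7 to 174). The most frequent single sequence of the mutant library held 3141 tags. Among the genes and clusters named here, only LSR1 had enough tags to hold it. Without molecular identifiers, the ratios of LSR1 and of the snRNAs together may thus rest largely on a single sequence. SNR19, the U1 snRNA on chromosome XIV (230105 to 230672), had 1862 and 14 tags, a ratio of 99.9 (59.4 to 183). The snoRNAs SNR13, SNR8, SNR4 and SNR51 had ratios of 57.5, 53.4, 54.3 and 84.9. With 0 wild type tags, SNR7-L (U5 snRNA) was at least 38-fold higher, SNR86 at least 34.3-fold and SNR17A (U3 snoRNA) at least 31.0-fold, each against a floor of 3 counts.

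At the other end of the ranking stood mRNAs of the translation machinery. RPL3, a protein of the large ribosomal subunit (chromosome XV, 444686 to 445849), had 195 wild type and 4 mutant tags, a 64.9-fold lower share (25.0 to 241). RPL24B (183 and 4 tags) was 60.9-fold lower and RPS3 (290 and 9 tags) 42.9-fold lower. TDH2, a glyceraldehyde-3-phosphate dehydrogenase, had 174 and 5 tags and was 46.3-fold lower (19.5 to 145). Left out were tags that matched at more than 1 place. At a fraction per place, these held 9 mutant and 1.5 wild type tags inside the ORF of TDH2, so its fold may be overstated. RPS31, which encodes a fusion of ubiquitin and a ribosomal protein, had 614 and 32 tags and was 25.6-fold lower. RPS25A had 234 wild type and 10 mutant tags, RPS11B 160 and 8, RPL8B 172 and 9, and RPS8B 93 and 3. NOP1, the fibrillarin that methylates ribosomal RNA, had 38 wild type and 0 mutant tags and was at least 16.9-fold lower.

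The split between higher and lower genes depended on the scaling. With shares of all placed tags, 122 genes were higher and 351 lower (25.8% of the called genes higher). TMM gave 197 and 121 (61.9%), DESeq2 size factors 196 and 128 (60.5%), and the total of mRNA 3′ end tags 285 and 18 (94.1%). Relative to shares of all placed tags, these scalings raised the log2 ratio of every gene by 1.26, 1.22 and 2.45. Counting each distinct end once, 42 genes were higher and 75 lower.

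**Figure D2:**
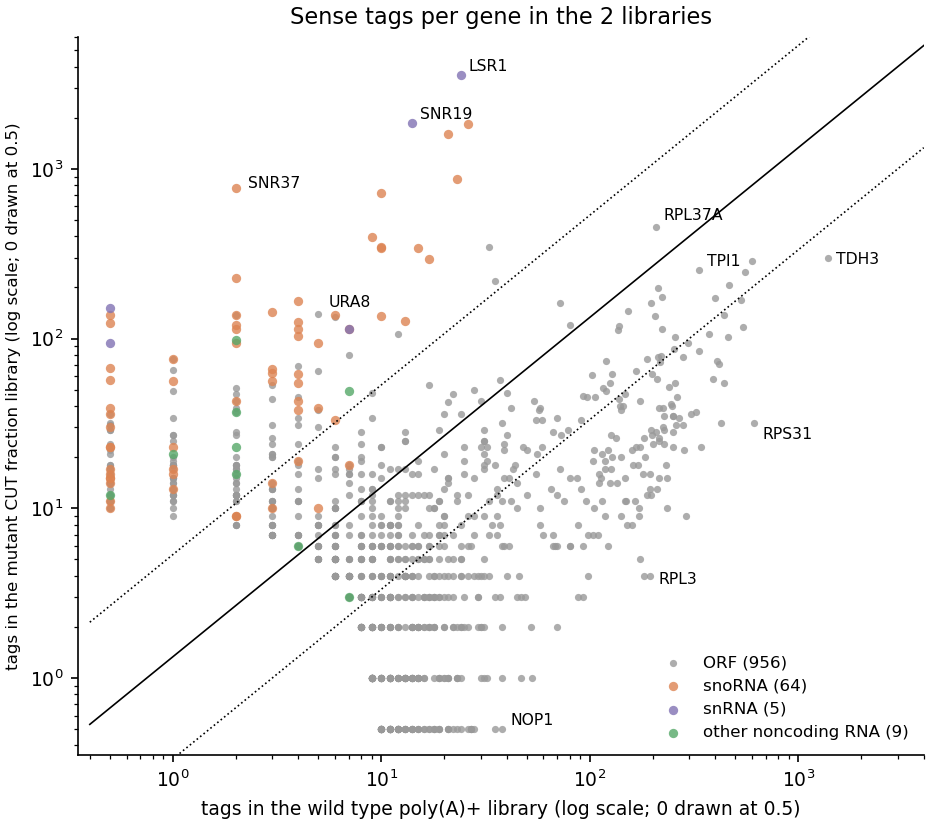
Sense tags per gene in the wild type poly(A)+ library (horizontal, log axis) against the mutant CUT fraction library (vertical, log axis), each point a gene with at least 10 tags over both libraries and counts of 0 drawn at 0.5; the solid line marks equal shares and the dotted lines 4-fold differences. Of 1034 genes, 122 were called higher and 351 lower with shares of all placed tags, against 285 and 18 with the total of mRNA 3′ end tags, where the ribosomal protein mRNAs as a sum turned from a ratio of 0.195 to 1.07.

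Among the gene lists, the snoRNAs and the snRNAs rose. Of 64 snoRNAs with at least 10 tags, 52 rose, 0 fell and 12 were not called, and SNR10 had 870 mutant and 23 wild type tags (ratio 28.4, 18.8 to 45.0). All 5 snRNAs with enough tags rose, SNR6 (U6) the least with 114 and 7 tags (ratio 12.2, 5.75 to 31.1). Both lists lay at percentile 100 of random lists matched on abundance, and both stayed higher under each scaling. The genes of nucleotide synthesis known for upstream start sites held more sense tags through early ends. Inside their ORFs lay 370 mutant and 11 wild type tags, while their 3′ end windows held 1 and 22. All 4 tested members were called higher, and the summed ratio of the list was 8.44 (5.91 to 12.4), at percentile 97.8. The fifth member, URA2, with 5 wild type and 0 mutant sense tags, was below the minimum of 10. Called higher were URA8, a CTP synthase (ratio 21.0, 8.80 to 65.8), IMD3 and IMD2, IMP dehydrogenases (ratios 8.58 and 8.45), and ADE12, adenylosuccinate synthase (ratio 6.63, 3.64 to 13.2). The percentile of this list was 96.2 with members of at least 10 tags only, 96.7 with TMM and 93.5 with mRNA 3′ end scaling, inside the central 95% of random lists.

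mRNAs of translation fell in share. Of 134 ribosomal protein genes tested, 98 fell and 2 rose (percentile 0), with a summed ratio of 0.195 (0.190 to 0.201), which turned to 1.07 with mRNA 3′ end scaling, where 5 rose and 9 fell. The 2 that rose were RPL7B (346 mutant and 33 wild type tags, ratio 7.87) and RPL18B (218 and 35 tags, ratio 4.68), both named after their values were seen. Of the mutant tags of RPL7B, whose intron holds the snoRNA gene SNR59, 336 lay before its 3′ end window. RPL41A had 600 wild type and 288 mutant tags (ratio 0.360) and RPP1B 555 and 245 (ratio 0.331), neither past the limit for a call. All 11 translation factor genes tested fell (percentile 0.06), with a summed ratio of 0.0810 (0.0677 to 0.0964). Among them TEF2, elongation factor 1 alpha, had 441 wild type and 55 mutant tags (ratio 0.0937), EFB1 214 and 26, ASC1 162 and 18, and HYP2 123 and 22. Of 14 ribosome biogenesis genes tested, 10 fell and 0 rose (percentile 0, summed ratio 0.0608, 0.0429 to 0.0840). Its members included GAR1 (53 wild type tags, 1 mutant tag) and NHP2 (98 and 4), proteins of H/ACA snoRNA particles, with NOP10 (46 and 4) and NSR1 (38 and 1). With mRNA 3′ end scaling 2 translation factor genes and 3 ribosome biogenesis genes were still called lower, and both sums stayed below 1 under each scaling.

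Other mRNA lists mostly moved with the bulk of mRNAs or held few tags, while the mating-type genes in sum fell further than mRNA 3′ ends as a whole. Of 15 glycolytic genes tested, 9 fell and 0 rose (percentile 31.0, summed ratio 0.209, turning to 1.14 with mRNA 3′ end scaling, where 2 rose and 2 fell). TDH3 had 1382 wild type and 299 mutant tags (ratio 0.162, 0.143 to 0.184), and GPM1, phosphoglycerate mutase, 546 and 117 (ratio 0.161), 90 of the latter inside the ORF. TPI1 (334 and 252 tags, ratio 0.567) and the aldolase FBA1 (196 and 161, ratio 0.617) were not called. Of 9 histone genes tested 5 fell and 0 rose (percentile 48.8, summed ratio 0.222, turning to 1.21 with mRNA 3′ end scaling, where 0 were called), HHF2 and HTB2 having 111 and 96 wild type against 16 and 11 mutant tags. HHF1, HHT2 and HTA1, named after their values were seen, also fell. In the heat shock list 2 of 4 tested genes fell, namely the chaperone genes HSC82 (67 and 7 tags) and SSA2 (23 and 1). The percentile of this list, 88.4, covered 18 members with tags, most of them below 10 tags. Its summed ratio of 0.299 turned to 1.64 with mRNA 3′ end scaling, where 0 were called. The 3 tested mating-type genes all fell (percentile 2.91, summed ratio 0.0710, below 1 under each scaling), with 2 called lower under TMM or DESeq2 and 0 with mRNA 3′ end scaling. The percentile of this list was 1.37 with TMM and 0.54 with mRNA 3′ end scaling, outside the central 95%. With random lists of protein-coding genes it was 3.88, inside the central 95%. They were the pheromone genes MF(ALPHA)2 (135 and 14 tags) and MF(ALPHA)1 (88 and 8) and the receptor gene STE3 (22 and 2). The 3 tested genes of phosphate and galactose use fell too (percentile 1.86, summed ratio 0.112), and none was called under the other scalings. Their percentile was inside the central 95% with mRNA 3′ end scaling (6.91), with members of at least 10 tags only (11.04) and with random lists of protein-coding genes (2.67). They were the phosphate transporter gene PHO84 (26 and 6 tags), SPL2 (23 and 2) and the acid phosphatase gene PHO3 (11 and 0). The count of 6 for PHO84 leaves out early mutant ends inside its ORF that were counted for another gene. In all, 12 lay in its first 500 nt, so its call may depend on how these ends are assigned.

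Among the exosome, TRAMP and Nrd1 complex genes, 3 of 6 tested fell and 0 rose (percentile 43.8), which turned to 2 higher and 1 lower with TMM or DESeq2 and to 2 higher and 0 lower with mRNA 3′ end scaling. These 2 were NRD1 and RRP6, the gene deleted in the mutant, whose tags all lay in its 3′ end window. The summed ratio of the list, 0.552, turned to 1.33 with TMM and 3.03 with mRNA 3′ end scaling. The exosome subunit gene SKI6 had 17 wild type and 0 mutant tags, at least 7.55-fold lower. The other 2 were CBC2 and, named after its values were seen, the exosome cofactor gene LRP1, with 11 wild type tags and 1 mutant tag each. CBC2 is the gene tagged in the mutant, and its tags all lay in its 3′ end window, so its count may not be comparable between the strains. Of 159 intron-containing genes tested, 67 fell and 4 rose, at percentile 99.7 of random lists. Those that rose were RPL7B, RPL18B and, named after their values were seen, HAC1 (22 mutant and 0 wild type tags) and PBA1 (18 and 0). Their summed ratio of 0.275 (0.267 to 0.283) turned to 1.51 with mRNA 3′ end scaling, where 37 were higher and 2 lower and the percentile turned to 0.15. The percentile was 53.4 with TMM and 77.5 with members of at least 10 tags only. RPL37A, which holds an intron, had 207 wild type and 457 mutant tags (ratio 1.66, 1.40 to 1.96) and RPL43A 466 and 207 (ratio 0.334), neither called. No meiosis gene reached 10 tags, with 2 wild type and 10 mutant tags over the list (percentile 98.0, but 96.4 with 2 tags added, 93.3 with TMM and 88.5 with mRNA 3′ end scaling). The only tRNA gene with 10 tags of a single match, YNCJ0008W, was not called (4 and 6 tags, percentile of the list 84.2), and Ty elements had 0 tags with a single match. The label check genes as a list lay at percentile 95, and 9 lists in all lay outside the central 95% of random lists, or 5 with members of at least 10 tags only.

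The 59 ORFs that rose did so mostly through ends far from their own 3′ end. For 37 of them most mutant tags lay inside the ORF, and 62.9% of their 2721 mutant sense tags did. Chosen after its values were seen, YDR157W on chromosome IV (769931 to 770332) had 137 mutant and 2 wild type tags in its 3′ end window (ratio 51.4, 14.0 to 429). The start of the next gene on the same strand, HOM2, an enzyme of threonine and methionine synthesis, lay 25 nt downstream. Of the 22 ORFs with most mutant tags in the 3′ end window, 11 (interval 30.7 to 69.3%) had such a start within 600 nt, against 34.4% (31.4 to 37.6) of other ORFs, intervals that overlap.

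A further comparison asked where RNAs ended relative to gene starts. Of the divergent and tandem ends, the opposite strand held 42.9% (42.0 to 43.8) of the mutant and 54.2% (51.9 to 56.4) of the wild type tags. These classes reach 500 nt upstream. They leave out opposite-strand ends inside a neighbouring ORF and same-strand ends in an mRNA 3′ end window. The shares and distances thus depend on the order of the classes and do not describe all ends upstream of ORFs. In the mutant library the median distance from the ORF start was 318 nt on the opposite and 151 nt on the same strand, against 142 and 96 nt in the wild type. The cluster at YDR524W-C, read below, held 256 of the 994 opposite-strand tags of the wild type library. Without it the wild type share was 46.7% (44.3 to 49.2) and the median opposite-strand distance 181 nt, against 42.4% and 322 nt in the mutant. For ORFs whose upstream neighbour lies on the same strand, the opposite-strand share was 44.4% (43.0 to 45.9) in the mutant and 47.1% (43.9 to 50.4) in the wild type. There the median same-strand distance in the mutant was 230 nt. The wild type share thus fell below 50 percent in these ORFs. Over all ORFs, with each distinct end counted once, the wild type share was 46.3%, against 48.2% in the mutant, so the order of the libraries turned.

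Around the starts of the 2878 ORFs with a same-strand neighbour upstream, distinct opposite-strand ends of the mutant library peaked 700 to 651 nt upstream, with 897 ends in the bin against a mean of 383 per bin. On the same strand distinct ends of the mutant library peaked in the bin that begins at the ORF start, with 632 ends against a mean of 226. Wild type ends on the same strand peaked 200 to 151 nt upstream with 716 ends. On the opposite strand of the wild type library the highest bin held 67 ends.

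**Figure D3:**
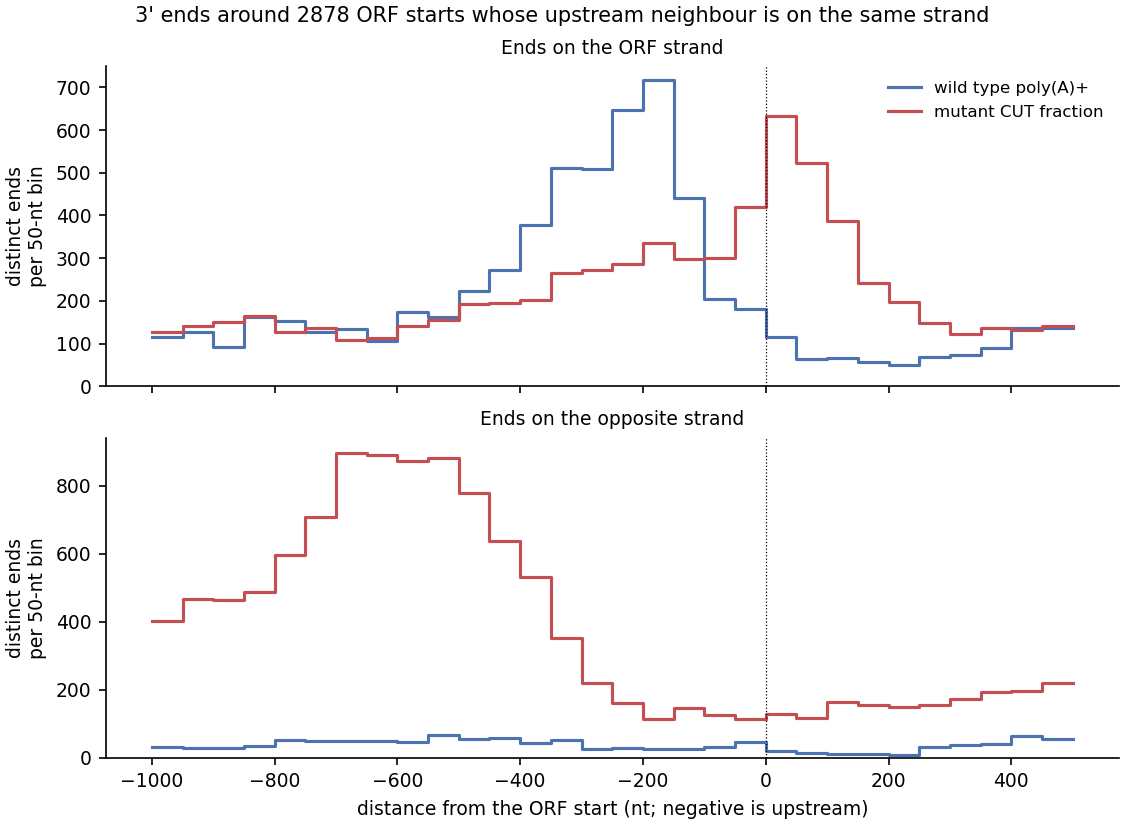
Distinct RNA 3′ ends per 50-nt bin (vertical axis) by distance from the ORF start in nt (horizontal axis) over 2878 ORFs whose upstream neighbour lies on the same strand, on the same and the opposite strand, for the wild type poly(A)+ and the mutant CUT fraction library; lines join the bins of single libraries. Opposite-strand ends of the mutant library peaked 700 to 651 nt upstream with 897 ends, and the wild type library had at most 67 in any opposite-strand bin.

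Genes with early ends were read at fixed loci. At TPI1, triose phosphate isomerase (chromosome IV, 555726 to 556472, minus strand), the first 500 nt of the ORF held 191 mutant and 4 wild type tags (ratio 35.9, 13.8 to 133). Its 3′ end held 59 mutant and 303 wild type tags (ratio 0.146, 0.109 to 0.194), and the opposite strand between 500 and 1000 nt upstream 50 and 2 (ratio 18.8, 4.93 to 159). Upstream of URA2, which encodes the first enzyme of pyrimidine synthesis (chromosome X, 165723 to 172367, minus strand), 717 mutant and 10 wild type tags lay within 500 nt on the same strand, a ratio of 53.8 (29.1 to 113). A further 455 and 7 lay between 500 and 1000 nt upstream, while the 3′ end of URA2 had 0 mutant and 4 wild type tags. URA8 had 140 mutant and 2 wild type tags in its first 500 nt (ratio 52.6, 14.3 to 438).

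For IMD3 (chromosome XII, 1002557 to 1004128), 116 mutant tags and 1 wild type tag lay within 500 nt upstream (ratio 87.1, 15.3 to 3470), and 80 and 3 in the first 500 nt of the ORF. IMD2 had 55 mutant and 15 wild type tags upstream (ratio 2.75, 1.53 to 5.25) and 44 and 1 in its first 500 nt. ADE12 had 108 and 1 upstream (ratio 81.1, 14.3 to 3232), 105 and 3 in its first 500 nt (ratio 26.3, 8.75 to 129), and 0 and 8 at its 3′ end. NRD1, an RNA-binding protein of transcription termination, had 20 and 1 upstream and 21 and 3 in its first 500 nt (ratio 5.26, 1.57 to 27.5). At PHO84, 12 mutant and 0 wild type tags lay in the first 500 nt, against 1 and 26 at the 3′ end. Of these mutant tags, 5 inside the ORF and 1 at the 3′ end counted for PHO84, and the rest for another gene. LYS20, homocitrate synthase, had 8 and 0 in its first 500 nt. SER3, an enzyme of serine synthesis, had 16 and 0 there, but these tags were classed as ends of SRG1, the noncoding RNA annotated across its start (21 mutant tags and 1 wild type tag in all). HRP1, an RNA-binding protein of mRNA 3′ end formation, had 18 and 8 upstream (ratio 1.69, 0.699 to 4.49), an interval that includes 1.

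**Figure D4:**
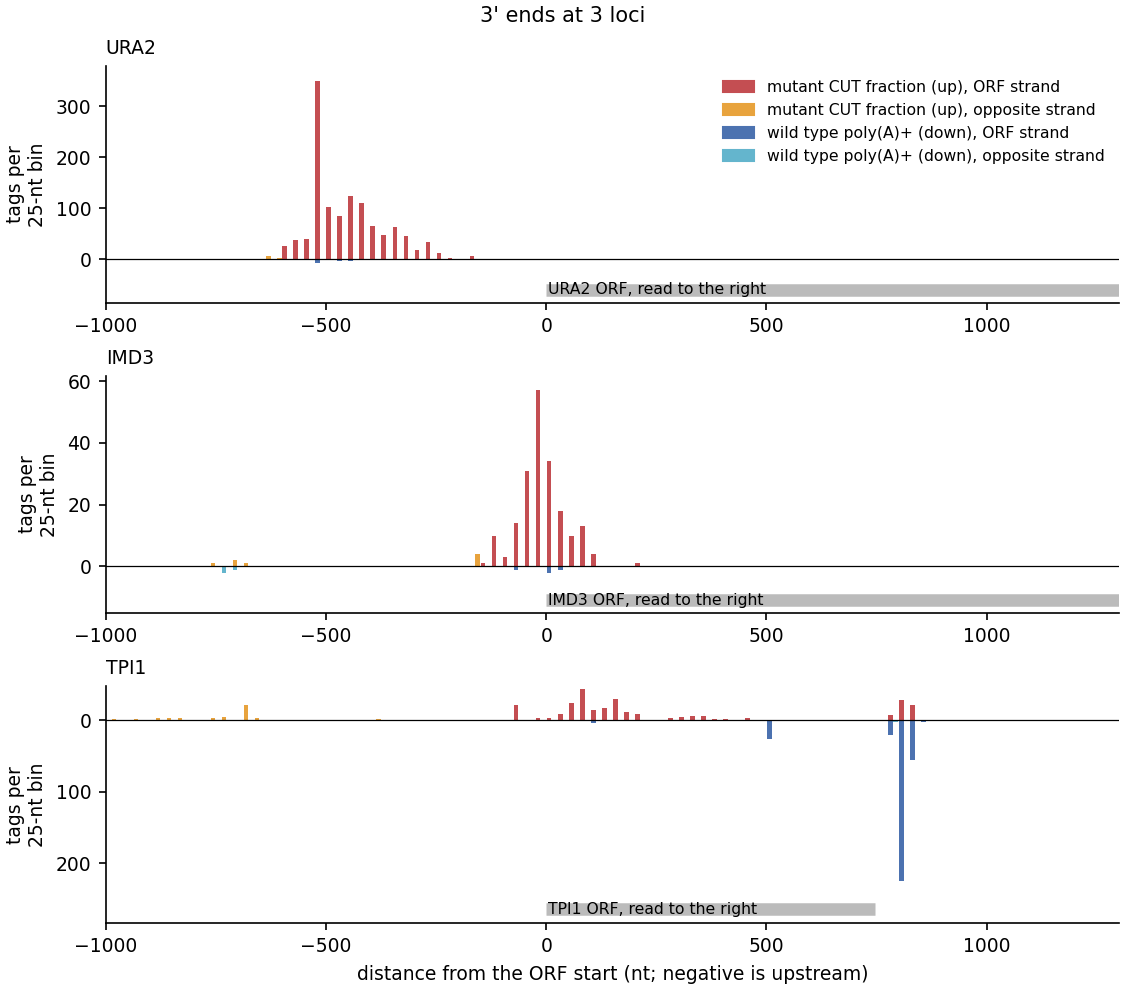
Tags per 25-nt bin (vertical axis, mutant CUT fraction upward and wild type poly(A)+ downward on the same scale) at URA2, IMD3 and TPI1, coloured by strand relative to the gene. The horizontal axis is the distance from the ORF start in nt, negative upstream, with each gene read to the right. The first 500 nt of TPI1 held 191 mutant and 4 wild type tags and its 3′ end 59 and 303, and the 500 nt upstream of URA2 held 717 and 10.

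Ends outside genes or antisense were also counted as clusters, each a run of ends at gaps of up to 50 nt that stops where its class does. Distances of clusters were measured from their peak. Of 1257 clusters with at least 5 tags, 1022 had at least 4 times the share in the mutant library and 77 in the wild type library by plain ratio, without a limit on the interval. Of these, 797 and 40 had 0 tags in the other library, and with counts of 0 set to the floor of 3 counts 406 and 47 reached 4 times the share. The 1022 held 26027 mutant tags (35.6%), and 488 of them were antisense to ORFs, 158 divergent, 179 tandem and 197 elsewhere outside genes. The cluster with most tags lay in the ribosomal RNA spacer (chromosome XII, 460367 to 460571, plus strand), with 3018 mutant and 32 wild type tags (ratio 70.8, 50.1 to 104). Upstream of URA2, a cluster at 172590 to 172964 on chromosome X had 1162 and 17 tags (ratio 51.3, 31.9 to 88.4). Antisense to the helicase gene ECM32, a cluster on chromosome V (544360 to 545002, minus strand) had 588 and 10 tags (ratio 44.2, 23.8 to 92.6). It lay 744 nt behind the start of BMH1, a 14-3-3 protein gene on the other strand. Counts of clusters moved with the minimum, from 1772 and 171 at 3 tags to 519 and 29 at 10 tags.

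Further antisense clusters faced starts of genes or followed a noncoding RNA. Antisense to PMD1, a cluster on chromosome V (425185 to 425480, plus strand) had 410 mutant tags and 1 wild type tag (ratio 308, 54.9 to 12190). It lay 320 nt past the snoRNA gene SNR4, which ends at 424883 on the same strand. Ends up to 300 nt past a noncoding RNA gene were counted for that gene, and this cluster began just past that window. Its start may thus be set by the window, and whether its ends are separate from those of SNR4 was not tested. A cluster antisense to VLD1 (chromosome IX, 381533 to 382133) had 448 and 4 tags, 172 nt behind the start of RPR2, a subunit of RNase P. Antisense to RED1, a gene of the meiotic chromosome axis (chromosome XII, 672350 to 672771), 242 and 2 tags lay 507 nt behind the start of RPS28B. Divergent from TRM82, a tRNA methyltransferase subunit, 322 and 8 tags lay 369 nt from its start (ratio 30.2, 15.2 to 70.6). Tandem clusters stood before ATG19, an autophagy receptor gene (130 mutant and 0 wild type tags, at least 32.5-fold higher), and PRC1, carboxypeptidase Y (128 and 3 tags, ratio 32, 10.7 to 157). A divergent cluster of the opposite kind lay at YDR524W-C, with 256 wild type and 88 mutant tags (ratio 0.258, 0.200 to 0.330).

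The last comparison asked how sharply ends were placed. In clusters thinned to 20 tags, the middle 80% of mRNA ends spanned a median of 21.8 nt (17 to 24.4, 291 clusters) in the wild type and 18.2 nt (13.1 to 24.7, 107 clusters) in the mutant library. Mutant ends outside genes or antisense spanned 119.7 nt (105.5 to 130.8, 269 clusters), and mutant ends of noncoding RNAs 107 nt (94.6 to 147.6, 60 clusters). In the wild type library 12 clusters outside genes or antisense reached 20 tags, too few for a comparison (3.3 nt, 0 to 141.6). In 88 mRNA clusters with 20 tags in both libraries, the medians were 17.1 nt in the wild type and 17 nt in the mutant, and 40 were wider in the mutant. With ends joined at gaps of 25 nt instead of 50 nt, the span of mutant ends outside genes or antisense was 69.6 nt.

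snoRNA ends lay past the annotated gene. In the mutant library 91.8% (91.3 to 92.3) of 10982 snoRNA tags ended more than 5 nt beyond the annotated 3′ end, at a median of 128 nt. Among the 288 wild type snoRNA tags the share was 91.0% (87.1 to 93.8), at a median of 105 nt. For 45 of 47 snoRNA genes with at least 20 mutant tags, most tags lay more than 5 nt beyond the end. For 11 of the 47 the most used single end lay within 5 nt of the annotated end, as for SNR10, where 91.0% of the 870 tags nevertheless lay more than 5 nt beyond it. SNR13 ended most often 146 nt past its gene, SNR37 145 nt, SNR4 158 nt and SNR8 79 nt.

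**Figure D5:**
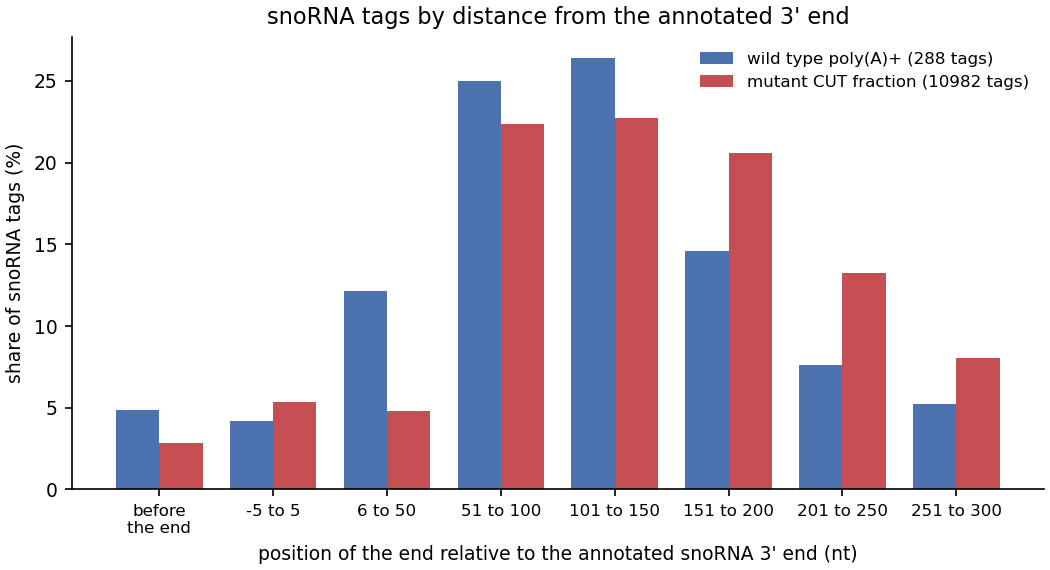
Share of snoRNA tags (percent, vertical axis) by distance of the RNA end from the annotated snoRNA 3′ end in nt (horizontal axis), for the wild type poly(A)+ (288 tags) and the mutant CUT fraction library (10982 tags). In the mutant library 91.8% and in the wild type library 91.0% of the tags ended more than 5 nt beyond the annotated end.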

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

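The tests of a few abundant loci and of host mRNAs were chosen only after the results were seen; the other tests of this part were chosen before.

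Some tags outside the comparisons took a larger share of the mutant than of the wild type library. On the extra replicon of the deposited file, numbered 18 and absent from the reference, the mutant library had 94 tags and the wild type 28, a ratio of 2.5 (1.63 to 3.97). Tags that matched at more than 1 place numbered 1820 in the mutant and 1042 in the wild type library, a ratio of 1.30 (1.21 to 1.41). Of these, 285 mutant and 38 wild type tags had all their places in tRNA genes or the 50 nt after them, a ratio of 5.59 (3.98 to 8.07). In other noncoding RNAs there were 27 and 3 (ratio 6.71, 2.07 to 34.6), and inside ORFs on the sense strand 276 and 113 (ratio 1.82, 1.46 to 2.29). Tandem upstream regions held 20 and 2 (ratio 7.46, 1.81 to 65.8), and other places outside genes 170 and 17 (ratio 7.46, 4.52 to 13.1). Not every part was higher in the mutant library: mRNA 3′ ends held 88 mutant and 120 wild type tags of this kind (ratio 0.547, 0.411 to 0.726). ORF antisense places held 186 and 162 (ratio 0.857, 0.690 to 1.06), divergent upstream regions 30 and 20 (ratio 1.12, 0.615 to 2.08), and places of different classes, the largest part, 738 and 567 (ratio 0.971, 0.869 to 1.09).

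Ends outside genes or antisense took a share 6.65 times larger in the mutant library. Oligo(dT) priming at A-rich genomic stretches, as the whole cause, is argued against, since the ratio was 7.46 (7.17 to 7.76) without ends next to 6 or more A in the 10 genomic nt downstream. An even background such as genomic DNA, as the whole cause, is argued against too. Of the distinct mutant ends 52.8% lay in chains of 5 or more, against at most 0.0511% in 20 random placements. This does not exclude such a background as a part of the ends. Leaving out the 10 clusters with most mutant tags, which held 19.5% of them, gave 6.07 (5.87 to 6.27), so a few abundant loci do not make the pattern. A candidate explanation is that the mutant fraction holds unstable RNAs that the wild type strain degrades, but strain, medium and RNA selection differ together here, so this stays open and untested.

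Mutant snoRNA tags ended beyond the annotated 3′ end in 91.8% of cases. Reads of host mRNAs, or of mRNAs that end upstream, are argued against as the whole cause. The share was 91.1% (90.3 to 91.8) over 6200 tags of 47 snoRNA genes. These genes had no same-strand ORF overlapping them or ending within 500 nt upstream. ORFs that begin downstream were not left out, so RNAs that start before such ORFs stay untested. A-rich priming is argued against by 91.3% (90.7 to 91.9) without ends next to such stretches. The interval of the wild type share, 87.1 to 93.8%, holds the mutant share, so a difference in this share was not detectable at this depth. Polyadenylated precursors of snoRNAs are a candidate source in both libraries, and the part of strain, medium and selection in their amount stays untested.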

How the results depend on the processing

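The alternatives that left out A-rich ends or ribosomal DNA tags, widened the noncoding RNA window to 600 nt, used mRNA 3′ end scaling or the floor of 3 counts for clusters, left out the cluster at YDR524W-C, split the intron-containing genes or drew random lists from protein-coding genes were chosen only after the results were seen. No paired analysis was possible because each group has 1 library. Over 49 alternatives, 1435 values were recomputed. Of 967 values for 88 single genes, 853 kept the call or its absence, 96 lost the call, 17 gained it and 1 called gene reversed. The ratio crossed 1 in 38 of them, over 16 genes, 37 times in genes without a call such as TPI1, FBA1, HTA2 and SSE1 with TMM. For the named clusters 235 stayed the same, 1 weakened and 1 strengthened, and for the percentiles of lists 86, 11 and 4, with 1 reversed. The ratio of ends outside genes or antisense (6.65) stayed above 1 throughout. It was 3.77 with distinct ends counted once, 8.94 without sequences seen once, 6.0 with multiple matches at a fraction per place, 3.18 with a 200-nt and 8.81 with a 500-nt mRNA window, 6.42 without ribosomal DNA and 7.46 without A-rich ends. The mRNA 3′ end ratio (0.183) was 0.188, 0.189, 0.172, 0.226, 0.190 and 0.169 for distinct ends, no sequences seen once, 200 nt, 500 nt, no ribosomal DNA and no A-rich ends. The noncoding RNA ratio (35) was 5.33 with distinct ends, 91.7 without sequences seen once and 27.7 with the 600-nt window. Genes called higher and lower (122 and 351) were 197 and 121 with TMM, 196 and 128 with DESeq2 and 285 and 18 with mRNA 3′ end scaling. Of the 473 calls, 243, 250 and 140 were kept under these. Since each scaling moves every gene by the same factor, its construction shows the cause of these counts and of RPL36B, which reversed to 1.30 with mRNA 3′ end scaling. The percentile of intron-containing genes also reversed there, to 0.15. The same factor for every gene cancels between a list and its random lists. By construction, the scaling also changes the mean abundance over both libraries on which random lists are matched, so other genes were drawn. This percentile thus depends on a matching variable that includes the mutant counts. Fewer genes or a new threshold by construction gave 233 lower genes at 20 tags, 547 lower at a ratio of 2, and 66 higher and 159 lower at a ratio of 8, while distinct ends gave 42 and 75. With members of at least 10 tags only, 5 lists instead of 9 lay outside the central 95% of random lists. The mutant opposite-strand share of divergent and tandem ends (42.9%) was 48.2% with distinct ends, 38.1% without sequences seen once, 44.4% for ORFs with a same-strand neighbour and 41.9% without A-rich ends. The wild type share (54.2%) was 46.3%, 60.1% and 47.1% under the former 3, which reversed it against 50 percent for distinct ends and same-strand neighbours. With distinct ends it thus lay below the mutant share. It also reversed to 46.7% without the cluster at YDR524W-C, so 1 locus set its side of 50 percent. The mutant median distance on the opposite strand (318 nt) was 302 nt with distinct ends and 335 nt without sequences seen once. On the same strand (151 nt) it was 124, 165, 230 and 160 nt under the 4 alternatives in that order. Clusters higher in the mutant and the wild type library (1022 and 77) were 1772 and 171 at 3 tags and 519 and 29 at 10 tags, as the minimum sets, and 44 were higher in the wild type with mRNA 3′ end scaling. With counts of 0 set to the floor of 3 counts they were 406 and 47, since clusters with few tags and none in the other library no longer counted. The span of ends was 16.55 nt for wild type mRNAs and 69.6 nt for mutant ends outside genes at a gap of 25 nt, 27.7 nt for mutant mRNAs and 156.55 nt outside genes at 100 nt, and 85.2 nt outside genes with 10 tags. Except where the construction is named, the cause was not tested. With 1 library per group and no molecular identifiers, depth limits the results to counting error, and genes with few wild type tags have wide intervals.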

Other observations

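The tests on ends before snoRNA genes, and the split of intron-containing genes, were chosen only after the results were seen, while those on opposite-strand ends and on ends inside ORFs were chosen before. The genes of this part that the rule does not name were chosen after their values were seen.

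The spliceosomal snRNAs and the snoRNAs, both higher in the mutant library, differed in where their RNAs ended. For LSR1 (U2), whose tags may be largely a single sequence, 97.2% of 3559 mutant tags lay within 5 nt of the annotated 3′ end. SNR19 (U1) had 80.8% of 1862 tags there and SNR14 (U4) 76.6% of 94. SNR6 (U6) had 33.3% of 114 tags there and ended most often 10 nt before its annotated end. SNR7-L (U5) ended most often 32 nt before its annotated end, and a shorter form of this RNA is known. In contrast, SNR13 had 99.4% of its tags more than 5 nt beyond the end, SNR37 97.4% and SNR4 98.5%. Exceptions among 47 snoRNA genes were SNR52, with 60.9% of 23 tags within 5 nt of its end, and SNR17B, with 27.3% of 55 tags there and 16.4% more than 5 nt beyond. RPR1, the RNase P RNA, had 56.5% of 23 tags there.

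RNAs also ended shortly before snoRNA genes, on the same strand. The 200 nt upstream of the 76 snoRNA genes held 1357 mutant and 59 wild type tags, a ratio of 17.3 (13.3 to 22.8). At least 20 mutant tags lay before 18 of the genes, with peaks 32 to 175 nt upstream and a median of 99 nt. SNR40 had 197 mutant and 11 wild type tags (ratio 13.4, 7.35 to 27.4) with a peak 70 nt upstream. SNR39B had 150 and 4 with a peak at 98 nt, SNR48 136 and 6 at 117 nt, and SNR64 102 and 5 at 102 nt. SNR190 had 107 and 4 at 48 nt, and SNR56 65 and 1 at 112 nt. SNR79 had 51 mutant and 0 wild type tags. Gaps between genes alone are argued against as the cause, since 1.14% of the distinct mutant ends outside genes or antisense lay there, against 0.0358 to 0.112% in 20 random placements. Read-through of an upstream gene as the whole cause is argued against, since 16 of 33 snoRNA genes with no same-strand gene ending within 500 nt upstream (48.5%, 32.5 to 64.8) had at least 5 mutant tags there, against 4.56% (3.95 to 5.26) of 3883 ORFs chosen alike. A-rich stretches lay next to 20.5% (18.4 to 22.7) of these tags, too few for priming to make the pattern. A candidate explanation is that 5′ leaders removed from snoRNA precursors are polyadenylated and enriched in the mutant fraction; the confounded design leaves this open.

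Opposite-strand ends may gather upstream of promoters because transcription starts there in both directions. If gaps between genes alone set their place, the share within 1000 nt upstream of the 2878 ORF starts with a same-strand neighbour would match random placement. It was 47.7% of 19579 distinct mutant ends, against 19.8 to 20.7% in 20 random placements and 29.7% in the wild type library. This argues against gaps alone, and the start sites themselves were not measured.

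Sense ends inside ORFs may mark early termination. Of 4521 distinct mutant ends inside ORFs longer than 600 nt, 89.3% lay in the first 500 nt, against 47.2 to 50.1% in 20 random placements over the same ORFs and 49.7% in the wild type library. This argues against ends spread evenly along ORFs, and whether strain, medium or RNA selection brought them out stays untested.

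Intron-containing genes that do not encode ribosomal proteins lay at percentile 100 of matched random lists, with 2 of 70 tested genes higher and 7 lower. Those that encode ribosomal proteins lay at percentile 6.83, with 2 of 89 higher and 60 lower, and ribosomal protein genes without an intron at percentile 0, with 0 of 45 higher and 38 lower. The percentile of all intron-containing genes was 77.5 with members of at least 10 tags only, 53.4 with TMM and 0.15 with mRNA 3′ end scaling. Under these settings the part that does not encode ribosomal proteins lay at 99.95 (its 70 members of 152), 100 and 99.78. The part that does lay at 22.41, 0.06 and 0, and ribosomal protein genes without an intron at 0 throughout. Of the 59 ORFs called higher, 3 (5.08%, 1.74 to 13.9) had a snoRNA or snRNA end within 1000 nt upstream on the same strand, against 8 of 897 others (0.892%, 0.453 to 1.75), intervals that overlap. The 3 were TRS31, which begins 280 nt past SNR13 and had 49 mutant tags and 1 wild type tag, SEN2 (17 and 0) and YTM1 (27 and 1).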
